A study of Homo sapiens with 6 samples.

How the data were processed

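Polyadenylated RNA of 6 cultures-by-siRNA samples was made into libraries with an Illumina TruSeq kit, per the labels' protocols. Cells were transfected for 48 hours with siNT or siWNK1 and then decidualized, and the labels give 3 culture numbers that occur once in each group. Equal numbers were read as the same culture in both groups. Per the submitters' processing notes, the tools TopHat, Picard, HTSeq and edgeR and the human genome build hg19 were used, and their versions, settings and strand handling are not given in the sources used here.

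The values analysed are the authors' comparison of siWNK1 with siNT, with 1 row per gene for 23710 genes. Per the file headers, the authors deposited the mean raw count of each group, a fold from edgeR, a mean log2 CPM value, a p-value and an FDR. A negative fold in the authors' deposited table is the negative of the reciprocal, since 7398 rows are negative and no absolute value is under 1. The mean counts multiplied by 3 came out whole within 0.01 in all 23710 rows of both groups, so they are plain means of 3 libraries. The FDR of the authors' deposited table is the Benjamini-Hochberg adjustment of the p-value over all 23710 rows, 4489 of them with 0 reads in both groups, with a largest difference of 0.0032 in log10 on recomputation. The authors' model, its scaling factors and any term for the culture are not given in the sources used here. No coordinates were used.

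Values per library were not analysed here, so the planned count model was replaced by the fallback fixed with it. The authors' fold was turned into a log2 fold, and a gene was called at an adjusted p under 0.05 in the authors' deposited table. Group means in CPM were computed from the authors' mean counts over the sum of all genes. That sum was 31630336 for siNT and 33236501 for siWNK1, the mean depth per library, or 94891008 and 99709502 reads over the 3 libraries, and the 10 highest genes held 5.03% and 4.75% of it. Their log2 ratio was set beside the authors' fold, and genes where these differ by more than 1.5 times are named with both values.

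Gene lists, the rule for named genes, the other thresholds and expression minimums and the ratio of mean counts were fixed before the data were examined, and the other scalings and list-test settings after. Of 31 lists 30 had members at 1 CPM or more on average, the 13155 genes used as background. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed normal score of the authors' p-value, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. An estimated correlation needs values per library and was not run. A one-sided Fisher's exact test of calls in either direction against the background, adjusted over the 30 lists, was added after the data were seen. It takes genes as independent of each other. Some genes are in more than 1 list, so the results of such lists are not separate observations. The named genes are WNK1, 7 decidual genes, the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and an official symbol, and up to 4 members of each list with the smallest p. Other list members in the text were chosen after their values were seen. The symbols of 28 rows read as calendar dates and those of 992 rows are LOC numbers, and neither kind is named. Genes linked to donor sex are left out of the printed tables.

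For other scalings, the spread of each gene was taken as its log2 fold over its normal score. A median, or the medians of 20 bins of abundance or transcript length, was then subtracted, and p-values were adjusted over the genes of at least 1 CPM. Transcript lengths and 3' UTR sequences came from GENCODE v29, matched by Entrez identifier. A length was found for 12693 of the 13155 genes, 96.5%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Calling from a fold, a known spread and the adjustment was tested on simulated data with 200 changed genes among 13155 in 20 draws. It recovered 67.6% of changes of 1.5-fold and 94.5% of 2-fold, with 4.3% and 4.7% of the calls false. No median or trend was planted or subtracted in that simulation, so the scalings themselves were not tested. The list test, on 100 draws of simulated scores for the same comparison, found 97.3% of lists shifted by 2 units and gave p under 0.05 in 6.65% of unshifted lists. Those scores were independent between genes, so false calls in lists of correlated genes were not tested. Some unshifted lists also share genes with shifted ones.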

Results

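RNA was sequenced from primary human endometrial stromal cells, the fibroblast-like cells of the uterine lining that differentiate into decidual cells under ovarian steroids and cyclic AMP. The cells carried either a control siRNA with no target (siNT) or an siRNA against WNK1 (siWNK1), a kinase known as a regulator of ion cotransport. They then received oestradiol, a synthetic progestin and a cyclic AMP analogue, and were collected on day 3 of that treatment. There were 3 libraries per group, from 3 cultures that each gave 1 siNT and 1 siWNK1 library, 6 libraries in all. The authors' mean counts summed to 31630336 reads in genes for siNT and 33236501 for siWNK1, the mean depth of a library in each group. The values below are the authors' group means, folds and adjusted p, with no value per library, so no SD between cultures is given and a change is called from the authors' adjusted p.

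WNK1 was examined first, because its transcript shows whether the siRNA acted in the group named for it. In the authors' deposited table the mean count of WNK1 was 9048 in siNT and 2515 in siWNK1, and its log2 fold was -2.03 (adjusted p = 4.9e-19). Scaled to the total of reads in genes, the same group means were 286 and 75.7 CPM, the count relative to the total of reads in genes, with a log2 ratio of -1.92.

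The question of the comparison was which transcripts of decidualizing cells depend on WNK1. The authors' deposited table lists 23710 genes, of which 3174 passed an adjusted p of 0.05 between siWNK1 and siNT, 2120 that rose and 1054 that fell. Changes of at least 2-fold were reached by 442 of the genes that rose and 299 of those that fell in the authors' deposited table. Rises were thus 66.8% of the calls, but this split moved with the scaling. The 13155 genes with at least 1 CPM had a median log2 fold of 0.10, and once that median was subtracted from every gene, 1279 genes rose and 1650 fell. Among genes of at least 8 on the log2 CPM scale, 40 rose and 100 fell in the authors' deposited table. From 4 to 6 on that scale, the same table had 784 rises and 252 falls.

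**Figure D1:**
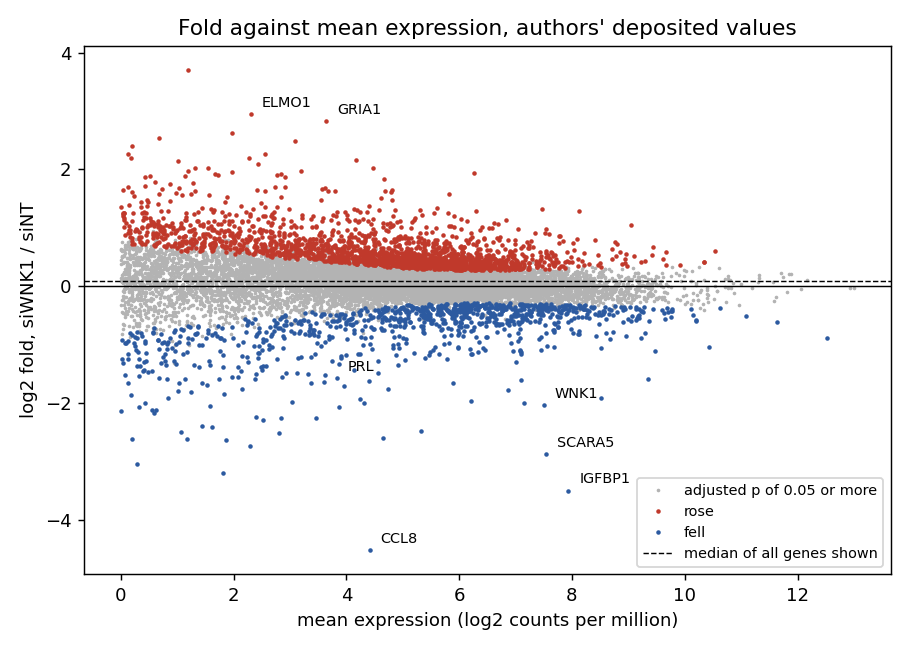
Each point is 1 gene with at least 1 CPM, with its mean expression (log2 CPM) on the x axis and the authors' log2 fold of siWNK1 over siNT on the y axis, coloured by whether it rose, fell or missed the adjusted p of 0.05. The dashed line is the median of 0.10, and WNK1 lies at -2.03.

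Among called genes with at least 5 CPM in the higher group and an official symbol, the 10 transcripts that rose most include genes of adhesion, signalling and neurons. ELMO1, an activator of Rac with DOCK proteins, rose from 1.15 to 8.73 CPM, a log2 fold of 2.95 in the authors' deposited table (adjusted p = 7.9e-26). GRIA1, a glutamate receptor subunit, had a log2 fold of 2.83, and KRTAP1-5, a keratin-associated protein, 2.62 in the authors' deposited table. The proteoglycan gene GPC4 rose by 2.16 and the focal adhesion scaffold gene NEDD9 by 2.03 on the log2 scale of the authors' deposited table. In the authors' deposited table, the remaining genes of these 10 were FAM19A2 (2.49), the adrenergic receptor gene ADRA2A (2.27), the synaptic adhesion gene NLGN3 (2.19), TNFAIP8L3 (2.09) and the integrin gene ITGA10 (1.97). IL33, at 1.78 CPM in siWNK1, missed that minimum and rose by 2.19 there, more than GPC4, TNFAIP8L3, NEDD9 and ITGA10.

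Under the same limits, the 10 transcripts that fell most included secreted factors and products of decidual and placental tissue. CCL8, a chemokine, fell by 4.51 in log2 fold in the authors' deposited table (adjusted p = 2.19e-06). The ratio of its mean counts was far smaller, -1.95 on the log2 scale, from 33.0 to 8.54 CPM. IGFBP1, the IGF-binding protein secreted by decidual cells, had a log2 fold of -3.49 in the authors' deposited table (adjusted p = 7.33e-12) and a ratio of mean counts of -2.13. For the ferritin receptor gene SCARA5 these values were -2.87 and -1.94, and for the cytokine gene IL1B -2.72 and -1.13, the first of each pair from the authors' deposited table. The growth factor gene EREG (-2.63), NKAIN1 (-2.59), the sulfotransferase gene CHST1 (-2.51) and the collagen gene COL6A6 (-2.41) also fell in the authors' deposited table. PSG6 (-3.18) and PSG1 (-2.47) complete these 10 falls of the authors' deposited table. The pregnancy-specific glycoprotein genes to which they belong are near-identical copies of each other, so the share of reads given to each is uncertain.

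Decidual marker genes went in both directions. Of 39 markers, all with at least 1 CPM, 13 fell, 7 rose and 19 did not pass in the authors' deposited table, or 15 falls and 11 rises adjusted over the list alone. The excess of falls depended on scaling, with 15 falls and 6 rises once the overall median was subtracted but 11 and 10 with the abundance trend removed and the median kept. PRL, the decidual hormone prolactin, fell from 21.3 to 7.29 CPM, a log2 fold of -1.57 in the authors' deposited table (adjusted p = 5.74e-08). WNT4, a WNT ligand needed for decidualization, fell by 0.77 (adjusted p = 0.000778), and HSD11B1, which activates cortisone, by 0.90 (adjusted p = 1.05e-06), as log2 folds of the authors' deposited table. SST and LEFTY2 fell with log2 folds of -1.91 and -2.00 in the authors' deposited table, against ratios of mean counts of -1.02 and -0.69. TIMP3, an inhibitor of metalloproteinases and the most abundant of these, went from 7458 to 4192 CPM, a log2 fold of -0.88 in the authors' deposited table.

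In contrast, ZBTB16 (0.97), PDK4 (0.92), BCL6 (0.74), FKBP5 (0.66) and HOXA10 (0.52) rose in the authors' deposited table. KLF9 rose by 0.39 and CEBPD by 0.37 there, and their calls ended when the overall median (CEBPD, 0.27) or the transcript-length trend and median (KLF9, 0.28) were subtracted. The transcription factor and receptor genes FOXO1 (0.17, adjusted p = 0.476), HAND2 (0.05, adjusted p = 1) and PGR (0.01, adjusted p = 1) and the ligand gene BMP2 (-0.20, adjusted p = 0.385) did not pass in the authors' deposited table. Markers held more calls than the other genes of at least 1 CPM, of which 21.4% were called over both directions (Fisher's exact test, one-sided, adjusted p = 0.000588). As a shift of the whole list downward, limma's cameraPR gave an adjusted p of 0.00475, with a range of 1.91e-07 to 0.083 under 5 other settings of that test.

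**Figure D2:**
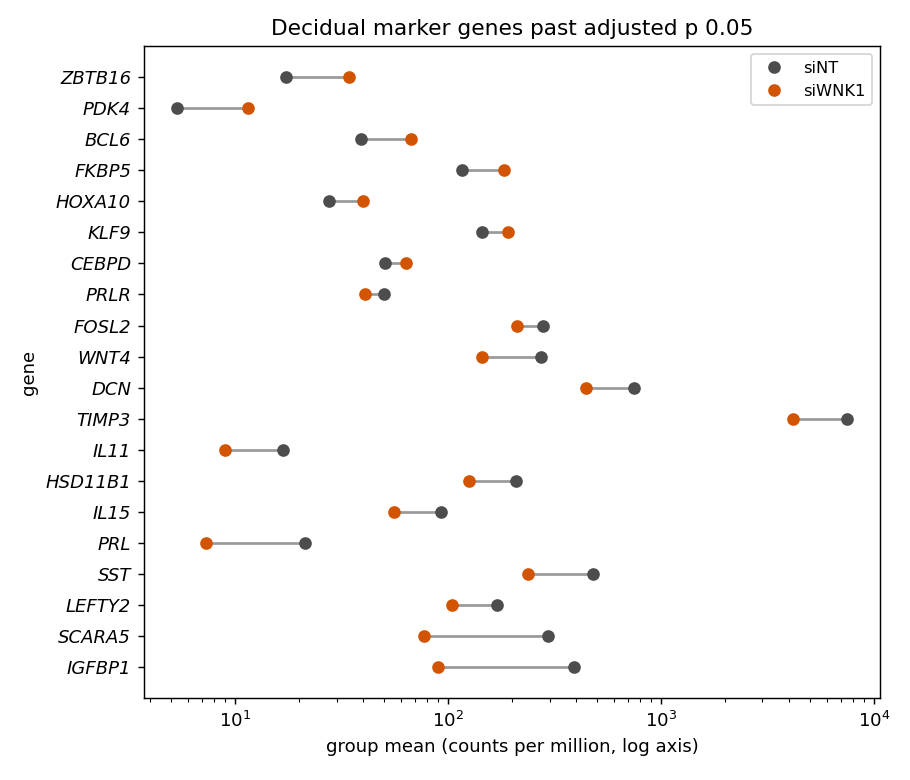
Group means of the 20 decidual marker genes past an adjusted p of 0.05, in CPM on a log axis, for siNT (grey) and siWNK1 (orange), ordered by the authors' log2 fold from IGFBP1 (-3.49) at the bottom to ZBTB16 (0.97) at the top. A line joins the means of each gene, and no error bars are drawn because the means come without one.

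Interferon-response genes and inflammatory cytokine genes were lower in siWNK1. Of 31 interferon-response genes, 17 fell and 1 rose in the authors' deposited table, or 19 and 1 adjusted over the list alone, and the list shifted downward (cameraPR, adjusted p = 8.05e-10, from 6.85e-15 to 4.56e-05 in the other settings). Among them IFI27 (-1.93), the antiviral enzyme gene OAS2 (-1.66), MX1 (-1.43) and ISG15 (-0.66) fell, whereas IFIT2 rose by 1.23 in the authors' deposited table. Of 20 cytokine and inflammation genes, 11 fell and 1 rose there, or 11 and 2 adjusted over the list alone (cameraPR, adjusted p = 1.59e-05, from 3.78e-15 to 0.0046 in the other settings). Besides CCL8 and IL1B, the prostaglandin synthase gene PTGS2 (-1.91), CCL7 (-1.86) and CXCL12 (-0.69) fell in the authors' deposited table. IL33, an alarmin cytokine, rose by 2.19 in the authors' deposited table (adjusted p = 1.74e-08).

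Leukocyte and endothelial markers were mostly below 1 CPM in these cultures. Of 16 leukocyte markers 4 reached 1 CPM and 0 passed, with a median log2 fold of -0.31 over those 4 (cameraPR, adjusted p = 0.253). Among endothelial markers 4 of 13 reached that level, with EGFL7 lower (-0.73) and ESAM higher (0.88, adjusted p = 0.0499) in the authors' deposited table (cameraPR, adjusted p = 0.455). The call for ESAM ended with the overall median subtracted (0.78). Of 8 epithelial markers at that level 1, CLDN4 (-1.13), fell in the authors' deposited table (cameraPR, downward, adjusted p = 0.551), while the median of the 8 was 0.10. Among 11 perivascular and smooth muscle markers, MYH11 (1.59), MCAM (0.80) and SYNPO2 (0.62) rose and CSPG4 (-0.44) fell in the authors' deposited table (cameraPR, adjusted p = 0.107). Stromal markers numbered 15, of which DCN (-0.88), ESR1 (-0.62), THY1 (-0.60) and LUM (-0.42) fell and HOXA10 rose in the authors' deposited table (cameraPR, adjusted p = 0.0698), with the call for LUM ended by removing the abundance trend and keeping the median (-0.26). Adjusted over the list alone, 0 leukocyte, 2 endothelial, 1 epithelial, 5 perivascular and 6 stromal markers passed.

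The lists of sterol synthesis and uptake and of hypoxia and glycolysis shifted downward. Of 23 genes of cholesterol synthesis and uptake, 5 fell and 0 rose in the authors' deposited table, the same number as when adjusted over the list alone. The list shifted downward (cameraPR, adjusted p = 3.64e-06, from 4.53e-06 to 0.00125 in the other settings). The largest falls in it were PCSK9 (-1.50) and LDLR (-1.11), both of low-density lipoprotein uptake, followed by the sterol reductase gene DHCR7 (-0.65), and SQLE fell by 0.39, in the authors' deposited table. With the overall median subtracted, 12 of the 23 fell, against 7 with the abundance trend removed and the median kept.

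Of 27 hypoxia and glycolysis genes, 5 fell and 2 rose in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR, downward, adjusted p = 0.00283, from 0.00231 to 0.0458 in the other settings). The falls included the glucose transporter gene SLC2A1 (-1.05), P4HA1 (-0.80), VEGFA (-0.73) and PDK1 (-0.55) in the authors' deposited table. With the overall median subtracted 11 fell and 1 rose, against 5 and 3 with the abundance trend removed and the median kept. The unfolded protein response list divided. Its chaperone genes SDF2L1 (-0.74), MANF (-0.52) and CALR (-0.48) were among 8 of 26 that fell in the authors' deposited table, while DDIT3 (0.82), ATF3 (0.72) and SESN2 (0.62), genes of the stress-induced transcription programme, were among 5 that rose. The calls for ATF3 with the abundance trend and median subtracted (0.54) and for CALR with that trend removed and the median kept (-0.32) ended. In the latter scaling 4 of the list fell and 6 rose, against 12 and 4 with the overall median subtracted. Adjusted over the list alone, 11 fell and 7 rose, and the downward shift of the whole had an adjusted p of 0.036 (cameraPR, from 0.0173 to 0.225 in the other settings, of which 1 of 5 passed).

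The ribosomal protein list showed a small common shift. All 42 of its genes missed the adjusted p of 0.05 in the authors' deposited table and adjusted over the list alone, and their median log2 fold was -0.19. The list as a whole was lower than other genes (cameraPR, adjusted p = 2.58e-07, from 3.61e-10 to 0.00796 in the other settings). The count of falls depended on scaling, with 22 of the 42 once the overall median was subtracted. It was 11 with the transcript-length trend and median subtracted, and 1 with that trend removed and the median kept. With the abundance trend removed, 0 fell, whether the median was kept or subtracted. Outside the list, RPL31 (-0.37), RPS28 (-0.35) and RPL18A (-0.32) fell in the authors' deposited table, named here after their values were seen, and RPL31 (-0.25) and RPL18A (-0.16) lost their calls with the abundance trend removed and the median kept. Many ribosomal protein genes have processed pseudogenes that share their sequence, which leaves their counts uncertain. The 31 nuclear genes of the oxidative phosphorylation list also had 0 calls in the authors' deposited table and adjusted over the list alone, with a median of -0.05 (cameraPR, downward, adjusted p = 0.0447, from 0.0046 to 0.202 in the other settings). Outside that list, COX7C (-1.05, adjusted p = 6.62e-10), COX7A2L (-0.47, adjusted p = 0.00165) and COX7A1 (-0.48, adjusted p = 0.0121), also named after their values were seen, fell in the authors' deposited table. The call for COX7A1 ended with the transcript-length trend removed and the median kept (-0.33). Mitochondrially encoded genes were not analysed here.

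Genes of the cell cycle and targets of the YAP and TEAD transcription factors were higher as groups. Of 31 DNA replication and S-phase genes, 11 rose and 0 fell in the authors' deposited table, or 14 and 0 adjusted over the list alone (cameraPR, adjusted p = 0.00124, from 3.38e-05 to 0.0437 in the other settings). CCND1 rose by 0.91 (adjusted p = 6.86e-06), the helicase gene MCM7 by 0.66 (adjusted p = 0.00223) and E2F1 by 0.82 (adjusted p = 0.0127) in the authors' deposited table, the last without a call once the abundance trend and median were subtracted (0.61). MCM2 (0.56) and POLE (0.60, adjusted p = 0.0119) also rose in the authors' deposited table, and the call for POLE ended with the transcript-length trend and median subtracted (0.46). With the overall median subtracted 7 of the 31 rose, and 4 with the abundance trend and median subtracted. Of 30 mitosis genes 4 rose and 0 fell in the authors' deposited table, or 15 and 0 adjusted over the list alone, with a median log2 fold of 0.45 (cameraPR, adjusted p = 0.00297, from 4.66e-05 to 0.0542 in the other settings). They were CENPF (0.68), CCNA2 (0.59), NDC80 (0.58) and KIF11 (0.51) in the authors' deposited table, and 2 rose with the overall median subtracted, which ended the calls for CCNA2 (0.49) and NDC80 (0.48). The call for KIF11 ended with the abundance trend and median subtracted (0.40), which left 1 rise. With the median kept, 8 rose once the abundance trend was removed and 7 once the transcript-length trend was removed.

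Of 20 YAP and TEAD targets, 9 rose and 1 fell in the authors' deposited table, or 11 and 2 adjusted over the list alone (cameraPR, adjusted p = 0.00297, from 4.81e-05 to 0.0437 in the other settings). CTGF went from 155 to 412 CPM, a log2 fold of 1.30 in the authors' deposited table (adjusted p = 2.12e-19). ANKRD1 (1.88), CYR61 (0.98) and AMOTL2 (0.72) also rose, and the coagulation factor gene F3 (-0.79) fell, in the authors' deposited table. The counts of the list depended on scaling, with 7 rises and 3 falls once the overall median was subtracted. They were the same with the transcript-length trend and median subtracted, against 13 and 1 with the abundance trend removed and the median kept. Of 20 genes of cell cycle inhibition and p53 response, 5 rose, among them BBC3 (1.21) and CDKN1B (0.52), and PLK2 fell (-0.48) in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR, adjusted p = 0.183). With the overall median subtracted, or the transcript-length trend and median, 3 of these genes rose and 2 fell.

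**Figure D3:**
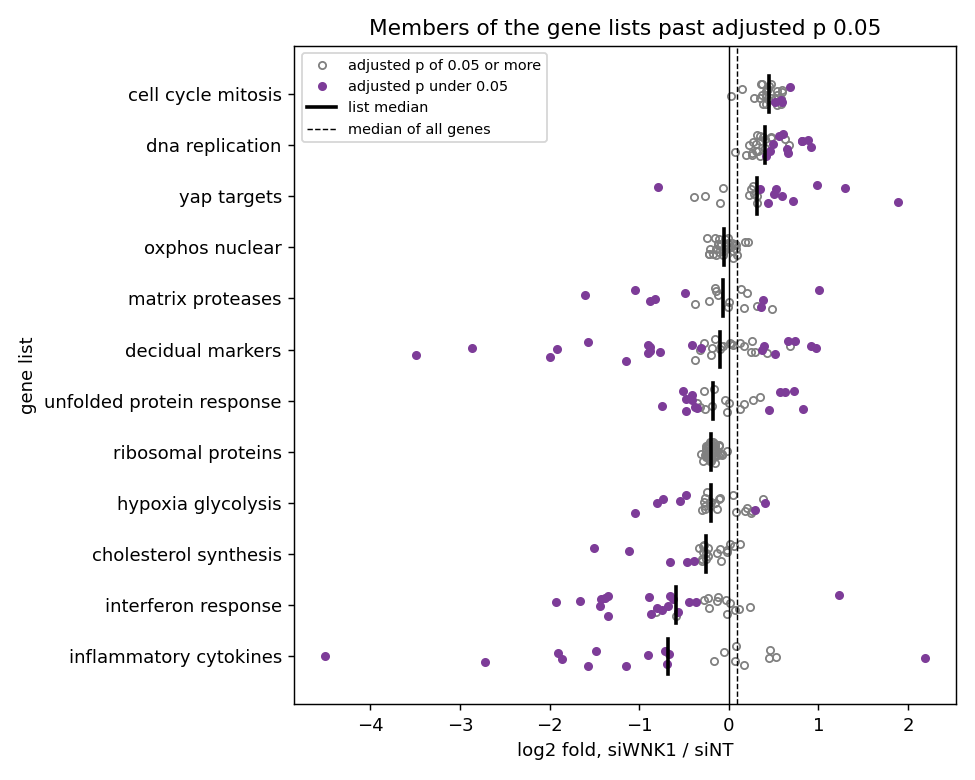
Each point is the authors' log2 fold of siWNK1 over siNT for 1 gene of the 12 lists past an adjusted p of 0.05 in cameraPR, filled where the gene passed an adjusted p of 0.05. The vertical scatter within a list has no meaning, thick bars are list medians, from 0.45 for mitosis genes to -0.68 for cytokine genes, and the dashed line is the median of 0.10 over all genes of at least 1 CPM.

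Signalling lists held calls in both directions and did not pass the main test for a shift of the whole list, which 4 of the 6 lists passed in 1 other setting. Of 25 genes of EGF-family ligands and MAPK feedback, 10 rose and 3 fell in the authors' deposited table, or 13 and 5 adjusted over the list alone (cameraPR, adjusted p = 0.176, from 0.0162 with genes of at least 5 CPM to 0.332 in the other settings). Calls of either direction were more frequent in it than in the background (Fisher's exact test, adjusted p = 0.00379). The feedback inhibitor genes SPRY2 (1.30), DUSP6 (1.12) and ERRFI1 (0.87) rose, and besides EREG the ligand gene NRG1 (-0.91) fell, in the authors' deposited table. Of 25 MAPK pathway kinases and factors, 3 rose and 2 fell there, or 7 and 3 adjusted over the list alone (cameraPR, adjusted p = 0.832, and Fisher's exact test, adjusted p = 0.814). MEF2C (0.54) and MAP2K3 (0.48) rose and MAP3K4 (-0.42) and MAP3K3 (-0.38) fell in the authors' deposited table, and the call for MAP2K3 ended with the overall median subtracted (0.38). The balance of this list turned with scaling, to 1 rise and 3 falls with that median subtracted and 5 and 2 with the abundance trend removed and the median kept. Among 29 TGF-beta and BMP genes, 8 rose and 4 fell in that table, or 9 and 4 adjusted over the list alone (cameraPR, adjusted p = 0.107, from 0.0258 with the abundance trend removed to 0.435, and Fisher's exact test, adjusted p = 0.0337). TGFB2 (1.63), SMAD3 (0.96) and SMAD7 (0.89) rose, and the activin-binding gene FST (-0.86) fell, in the authors' deposited table.

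Of 25 WNT pathway genes 7 rose and 7 fell in the authors' deposited table, or 9 and 7 adjusted over the list alone (cameraPR, downward with a mean normal score of 0.232, adjusted p = 0.551, and Fisher's exact test, adjusted p = 0.00125). The receptor genes FZD7 (1.96), FZD4 (0.60) and FZD1 (0.77) rose, and RSPO3 (-1.22), WNT2 (-0.70) and WNT4 fell, in the authors' deposited table. Of 27 FOXO and insulin pathway genes, 12 rose and 3 fell in the authors' deposited table, or 13 and 3 adjusted over the list alone (cameraPR, adjusted p = 0.0698, from 0.00506 with the abundance trend removed to 0.642, and Fisher's exact test, adjusted p = 0.00113). FOXO3 (0.74), TXNIP (0.64) and PIK3R1 (0.56) rose in the authors' deposited table, where IGFBP1 fell. With the transcript-length trend and median subtracted 7 of the FOXO list rose and 3 fell, against 14 and 2 with the abundance trend removed and the median kept. Of 19 steroid-responsive genes, 8 rose and 2 fell in the authors' deposited table, or 9 and 4 adjusted over the list alone (cameraPR, adjusted p = 0.0698, from 0.00631 with the abundance trend removed to 0.355, and Fisher's exact test, adjusted p = 0.0104). Their balance moved with scaling, to 8 rises and 5 falls with the overall median subtracted. It was 6 and 5 with the transcript-length trend and median subtracted, and 9 and 2 with the abundance trend removed and the median kept. TSC22D3, a glucocorticoid-induced gene, rose by 1.08 (adjusted p = 1.34e-16) and KLF15 by 1.15 (adjusted p = 0.000158) in the authors' deposited table, and HSD11B1 fell. Of the called steroid-responsive genes, FKBP5, ZBTB16, KLF9 and HSD11B1 are also decidual markers. TXNIP and IRS2 are also in the FOXO list, and ERRFI1 is in the EGF list. IGFBP1, PDK4 and BCL6 of the FOXO list are decidual markers too. The results of these lists thus rest partly on the same genes.

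Matrix and adhesion genes went in both directions. Of 33 fibrillar and basement-membrane matrix genes, 6 rose and 5 fell in the authors' deposited table, or 7 and 6 adjusted over the list alone (cameraPR, downward against other genes, adjusted p = 0.558, with a median log2 fold of 0.06). With the overall median subtracted 4 rose and 6 fell, and with the abundance trend removed and the median kept 10 rose and 4 fell. POSTN (1.20), THBS1 (1.05), FN1 (0.61) and the elastin gene ELN (0.60) rose, while the proteoglycan gene VCAN (-1.03) and COL6A3 (-0.61) fell, in the authors' deposited table. Of 20 matrix proteases and inhibitors, 5 fell and 3 rose in that table, or 5 and 4 adjusted over the list alone (cameraPR, downward, adjusted p = 0.00726, from 0.0111 to 0.219 in the other settings). ADAMTS4 (-1.60), MMP10 (-1.05) and ADAMTS9 (-0.83) fell in the authors' deposited table, and MMP11 (1.01) rose. With the overall median subtracted, 1 of the list rose and 5 fell, and with the abundance trend removed and the median kept 6 rose and 5 fell. Of 21 adhesion and migration genes, 8 rose and 2 fell in the authors' deposited table, or 9 and 2 adjusted over the list alone (cameraPR, adjusted p = 0.113, from 0.00737 with the abundance trend removed to 0.378, and Fisher's exact test, adjusted p = 0.0208). NCAM1 (1.90) and the integrin genes ITGA4 (1.01), ITGA2 (0.78) and ITGA11 (0.75) rose in the authors' deposited table. Of 20 contractile genes, 4 rose, MYLK (0.68), CNN1 (0.54), PALLD (0.48) and LMOD1 (0.42), and 0 fell in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR, adjusted p = 0.284, from 0.00554 with the abundance trend removed to 0.642 in the other settings). With the overall median subtracted 4 contractile genes rose, and 9 with the abundance trend removed and the median kept.

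Genes of the WNK pathway other than WNK1 rose where they passed. Of 15 genes of the WNK pathway and cation-chloride cotransport, 4 besides WNK1 passed and all 4 rose in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR, adjusted p = 0.84, and Fisher's exact test, adjusted p = 0.323). Both tests included WNK1, the siRNA target, among the 15, so neither tests the other genes alone. The 4 that rose were the ubiquitin ligase adaptor gene KLHL3 (0.75, adjusted p = 0.0241), the cotransporter gene SLC12A2 (0.41, adjusted p = 0.00314), the kinase gene STK39 (0.39, adjusted p = 0.00915) and CAB39 (0.33, adjusted p = 0.0308) in the authors' deposited table. The calls for CAB39 with the overall median subtracted (0.23) and for KLHL3 with the abundance trend and median subtracted (0.56) ended, so the 4 rises are not all firm. Of 13 osmotic stress genes 3 rose and 2 fell in that table, or 4 and 2 adjusted over the list alone (cameraPR, downward with a mean normal score of 0.474, adjusted p = 0.84). The transporter genes SLC38A2 (0.74), SLC6A6 (0.51) and SLC9A1 (0.39) rose and SLC6A12 (-1.28) fell in the authors' deposited table, and the call for SLC9A1 ended with the overall median subtracted (0.29), which left 2 rises and 3 falls in the list. Of 23 autophagy and lysosome genes, GABARAPL1 (0.60) and ULK2 (0.42) rose and CTSL1 (-0.54) fell in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR, adjusted p = 0.691). The call for ULK2 ended with the transcript-length trend and median subtracted (0.27).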

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

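The thresholds, expression minimums and the ratio of mean counts were chosen before the data were examined, and the other scalings and list-test settings after. Whether the authors' p-values are paired by culture is not given in the sources used here. No paired analysis was possible here, because the values are group means and the authors' statistics, with none per library. For the same reason the culture block, other size factors, DESeq2, voom, fry, an estimated correlation, leaving out libraries or pairs, and other splits of the libraries were not run. The 3174 calls became 1858 at an adjusted p under 0.01 and 1666 with a minimum change of 1.5-fold, since both are stricter. They ranged from 2702 to 4138 over the other thresholds, minimums and scalings. The share of calls that rose, 66.8%, went below 50% with the overall median subtracted (43.7%), with the abundance trend and median subtracted (45.1%) and with the transcript length trend and median subtracted (42.9%). In the other settings it stayed between 65.0% and 69.9%. WNK1 stayed between -1.91 and -2.14 and called wherever it was tested. Decidual markers past the threshold numbered 15 to 24, against 20. Over all settings, 65 values of named genes lost their call, 43 gained one and none changed sign with a call. In the ratio of mean counts, 20 named genes moved by more than their spread. The 12 lists past the threshold became 7 with a preset correlation of 0.05, a wider assumed spread. The same 7 lists passed in all 5 settings: DNA replication, YAP targets, interferon response, cytokines, cholesterol, hypoxia and ribosomal proteins. Over the 30 lists and 5 settings, 15 results lost a call and 6 gained one, steroid, contractile, adhesion, TGF-beta and FOXO genes with the abundance trend removed and EGF and MAPK feedback genes at 5 CPM. Depth was not the limit for WNK1, at 2515 reads per siWNK1 library, but lists with 4 measured genes are weakly tested.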

Other observations

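Beyond the lists fixed beforehand, gene families defined by the stem of their symbols were tested with cameraPR, all after the data were seen, as were the tests on abundance, length and fold gaps below. Of 118 families with at least 12 genes at 1 CPM, 8 passed an adjusted p of 0.05, 7 downward and 1 upward. The SEC genes, most of which serve protein export from the endoplasmic reticulum, shifted downward. Of the 26, 11 fell and 1 rose in the authors' deposited table, with a median log2 fold of -0.28 (adjusted p = 5.66e-05, from 8.2e-05 to 0.033 in the 5 other settings). The coat protein genes SEC24A (-0.59), SEC31A (-0.42) and SEC23A (-0.42) and the translocon gene SEC61G (-0.52) fell, and SEC31B (0.70) rose, in the authors' deposited table. With the abundance trend removed and the median kept, 6 SEC genes fell, and 7 of the 11 falls lost their calls, SEC31A and SEC23A among them (-0.26 each). With the overall median subtracted, 16 fell. The other families that shifted downward were RPL (adjusted p = 4.69e-05), RPS (0.000189), SLC (0.0184), COX (0.0218), TM (0.0246) and EIF (0.0313). RPL and RPS share members with the ribosomal protein list above, so they are not separate observations. Their stems also take in other genes, such as the pseudogene RPL32P3 and the kinase gene RPS6KA5. With a preset correlation of 0.05 the adjusted p was 0.055 for RPL, 0.0696 for RPS, 0.43 for SLC, 0.257 for COX, 0.186 for TM and 0.43 for EIF, and 0.0304 for SEC.

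The ARHGAP genes, which encode GTPase-activating proteins of the Rho family, shifted upward. Of 28, 14 rose and 1 fell in the authors' deposited table, with a median log2 fold of 0.40 (adjusted p = 0.026, from 0.00522 to 0.335 in the 5 other settings). ARHGAP20 (1.01) and ARHGAP18 (0.72) rose, and ARHGAP21 (-0.91) was the member that fell, in the authors' deposited table. Among the risers, ARHGAP5-AS1 is antisense to ARHGAP5, and without strand its reads and those of its partner are not separable. With the median subtracted together with the abundance trend, or with the length trend, 7 ARHGAP genes rose and 2 fell, and the first ended the call for ARHGAP5-AS1 (0.42).

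More genes rose than fell, and the tables show how far this rests on scaling. Taking out the trend of the fold with abundance while keeping the overall median left rises at 69.9% of the calls, and taking out the trend with transcript length left them at 66.4%, and subtracting the overall median of 0.10 brought them to 43.7%. These outcomes are largely set by keeping or removing the median itself, so none of them decides. A shared scaling offset, a trend with abundance or length, and a real small rise of most transcripts in siWNK1 cells all stay open. Genes of at least 8 on the log2 CPM scale held 42.8% of the counts in siNT and 40.9% in siWNK1.

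The falls could have come from siRNA seed matches in the 3' UTRs of other transcripts. All 7-base words were searched in 12226 genes with an annotated 3' UTR, 895 of them fallen, against 100 permutations within strata of UTR length and abundance. The 4 words most in excess were together 3.72 percentage points above a permuted mean of 16.3, where falls made mainly by seeds were set to give at least 20. With planted words, 50% of the falls gave 22.3 points and 20% gave 1.12, each from 1 draw of 4 words with equal shares. The planted words were rarer than the 4 leading words, which occurred in 11.85% to 26.62% of the genes not called as fallen. The result thus argues only against 4 words as rare as those planted behind 50% of the falls. More words, commoner words or unequal shares were not simulated, so seeds as the main source are not excluded. A smaller share stays open, since 1 of the 100 permutations reached the observed sum. The largest excess of a single word was 5.71 points, below the highest permuted value of 6.33. Genes with each of the 4 words differed in median log2 fold from genes without it by 0.014, -0.044, 0.007 and 0.024. A dependence on WNK1 itself was not tested apart from the siRNA.

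For 29 genes the authors' log2 fold lay more than 0.5 from the ratio of mean counts, whereas 94.3% of 13155 genes lay within 0.1. The largest gaps were those of CCL8 (-2.56), IL1B (-1.59), IGFBP1 (-1.36) and LEFTY2 (-1.31), and 27 of the 29 folds were negative. A prior count that shrinks folds is argued against as the source of these gaps, because the authors' fold was the larger in 89.7% of the 29. This does not say that no prior count was used. Genes with 1 read in a group and none in the other had finite folds, from 3.35 to 3.74. Genes with 1 read in a group fell into 3 classes of fold per group, as 3 libraries would give. Their shares, from 21.6% to 39.3%, were taken to bound the spread of depth. In siNT the shares were 38.8%, 24.7% and 36.5% in order of rising fold. They do not follow the fold steadily, so they may not measure depth alone. The bound allows a gap of 0.85, or 1.28 at the 95% Wilson limits, and the 4 genes named above lay beyond it, LEFTY2 by little. This argues against depth for them only as far as the shares measure depth. For the other 25 genes depth stays open. A fit that averages the response over cultures, with most counts of these genes in a culture that responded less, may be the source, but no value per library was used to decide for the 29.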
